A study of Mus musculus with 6 samples.

How the data were processed

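Total RNA from mouse embryonic stem cells (mESCs) that were wild type or knocked out for Setd2 was hybridised to Affymetrix mouse genome arrays, with 3 arrays per genotype that the labels call biological repeats. The cells were grown on feeder cells, which the growth protocol removed as far as possible by letting them settle on gelatin and by 1 passage without feeders. The deposited table held 45037 probe sets on 6 arrays, and every array was assigned to its genotype and replicate number from its title.

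The deposited values were log2 signals: per the submitters' processing notes they came from MAS5, the Affymetrix algorithm that turns the probes of a probe set into 1 signal, and no version was given in the sources used here. The scale was settled from the values. After raising 2 to each value, the trimmed mean with 2% taken off each end lay between 497.0 and 497.3 on all 6 arrays, as it does after MAS5 scaling to a common target. Between 280 and 454 values per array were exactly 0, the log2 of a signal of 1. The array medians lay between 6.09 and 6.22. The plan fixed before the data were examined provided for log2 values by using them as they are, so no pseudocount and no further normalization between arrays were applied. Detection calls were not used here, so the fold of a dim probe set is the ratio of its MAS5 signals and no bound against background was derived. The 3' to 5' signal ratios of control probe sets, planned as a sign of RNA quality, were not analysed here. For arrays, depth in the sense of read counts does not apply, and the number of arrays limits the precision.

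Genes were named from the platform annotation, with 34741 symbols brought up to date through their gene identifiers against a RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 34945 named 1 gene, 932 named several and 9160 were unnamed here. The table served only for symbols, for the chromosome of a gene and for gene order along a chromosome. The array values carried no genome build, so no coordinates are given.

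Probe sets with a mean log2 value over all 6 arrays below the 40th percentile (5.27) were left out, which left 27022 probe sets for testing. Knockout minus wild type differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Errors are standard deviations (SD) over the 3 arrays of a genotype or standard errors (SE) of the fitted difference. For tests on genes, each of the 12915 genes was represented by its tested probe set with the highest mean. Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. In all 35 lists were written before the data were examined, from knowledge of stem cells, of H3K36 methylation and of feeder cells. Of these, 34 had the minimum of 5 tested genes. The genes of each of 20 chromosomes were tested in the same way.

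The genes named in the text followed a rule fixed before the data were examined. It took Setd2, the 10 largest rises and the 10 largest falls past the threshold among genes whose knockout values all lay on one side of the wild type values, each gene at its tested probe set with the highest mean, and up to 4 members past the threshold from each list described, or the 2 brightest members where none passed. In the ranking, provisional, clone and accession names and probe sets naming several genes were passed over. It also took Pou5f1, Nanog, Sox2, Gata6, Gata4, Sox17, Pdgfra, Fgfr1, Fgfr2, Fgfr3 and Fgf4 whatever their result. Probe sets of 1 gene that passed the threshold in opposite directions were to be named too. Genes outside the rule are marked as chosen after their values were seen.

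Both genotypes carried replicate numbers 1 to 3 in the titles, and nothing in the labels said what a number shares. Deviations from the genotype means over the tested probe sets correlated between arrays of the same number at r = 0.50 for number 1, 0.23 for number 2 and 0.24 for number 3, across probe sets, which are not independent replicates. All 3 lay above 0.1, the bound set for treating the numbers as pairs. Arrays of unlike number gave r from -0.37 to 0.23, and wild type 2 with knockout 3 correlated as strongly as wild type 2 with knockout 2. Deviations sum to 0 within a genotype, so a split of number 1 alone raises the correlations among numbers 2 and 3. The check therefore shows no clear pairing of number 2 with 2 or of 3 with 3. The fit without a block was the one fixed before the data were examined, and the fit with the replicate number as a block stands beside it for the counts over all probe sets and in the lists described, where these differ.

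The fit was tested on simulated data drawn at the mean of each probe set, with 200 probe sets changed by known amounts. The noise was normal and independent between probe sets, with the spread given by limma's intensity trend instead of each probe set's own. Without any split by array number, 50.0% of changes of 0.5 log2, 84.3% of changes of 1 log2 and 92.9% of changes of 2 log2 were recovered among the 27022 probe sets, with 10 false calls among 164. With the split by number added, the fit without a block recovered 3.33%, 25.7% and 55.7%, with 0 false calls among 59. The block recovered 33.3%, 72.9% and 97.1% there, with 13 false calls among 152. In 20 simulated tables, camera called a list of 25 genes shifted by 0.5 log2 in 20, and called 1 of 600 lists that had not been shifted. The genes of these tables were drawn independently and without the split by number. The rates of the fit and of camera therefore do not carry over to the real arrays, whose genes are correlated and differ in spread at like intensity.

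Alternatives fixed before the data were examined were pseudocounts on the linear scale, no filter and a stricter filter at the 60th percentile, quantile normalization, centring on the array medians, eBayes without the trend or made robust, array weights, leaving out probe sets that can detect several transcripts, the mean of a gene's probe sets, the estimated correlation, the replicate block and leaving out each array. Alternatives chosen after seeing the data were a block for number 1 against numbers 2 and 3, leaving out both arrays numbered 1, leaving out the genes of chromosomes 8 and Y, and a pseudocount at the 25th percentile. The fits with a single array left out had no block, so the split by number was unbalanced between the genotypes there. Calls lost in them can reflect that as well as the smaller group.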

Results

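Gene expression was measured on 6 microarrays, 3 from wild type and 3 from Setd2 knockout mESCs, pluripotent cells derived from the early mouse embryo. Setd2 is the methyltransferase that trimethylates histone H3 at lysine 36 (H3K36me3) along transcribed genes. The design set out to find deregulated genes needed for differentiation into primitive endoderm, the extraembryonic layer that forms beside the epiblast in the blastocyst. Values are log2 MAS5 signals. The arrays differed by replicate number as well as by genotype: the first principal component (38.0% of variance) parted the arrays numbered 1 from those numbered 2 and 3 in both genotypes, and the second (28.9%) parted the genotypes.

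**Figure D1:**
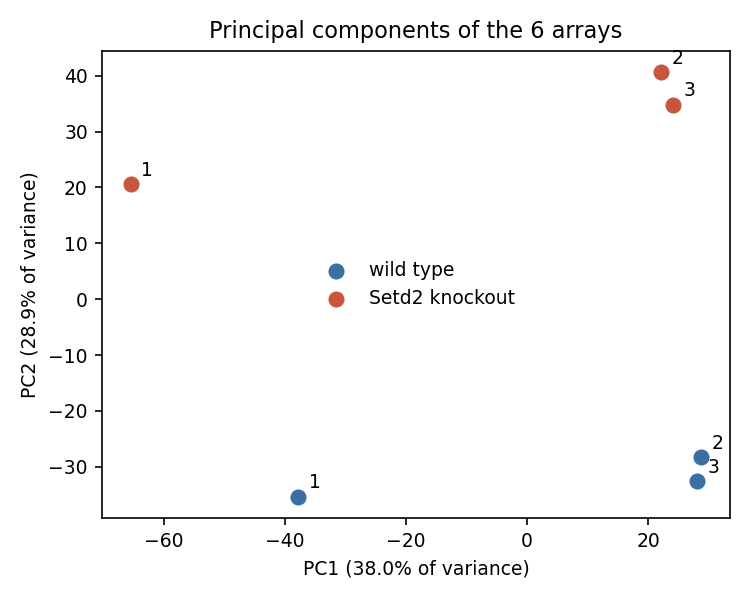
Scores of the 6 arrays on the first 2 principal components, labelled by replicate number, with wild type in blue and Setd2 knockout in red; the axes give the share of variance. Both arrays numbered 1 lie at the left, with scores of -37.8 and -65.4 on the first component, and the genotypes lie apart on the second.

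The targeted gene came first. The single Setd2 probe set (1428555_at) read 10.30 ± 0.01 in wild type and 9.49 ± 0.12 in knockout cells (mean ± SD, n = 3 each), and fell by 0.82 ± 0.12 (SE) on the log2 scale, a signal 1.76-fold lower (limma adjusted p = 0.0272; 0.000744 with the replicate block). All 3 knockout arrays, at 9.37, 9.50 and 9.60, lay below all 3 wild type arrays. The labels do not give the deleted part of the gene, so this probe set checks the genotype only if it lies inside that part. The call was lost without wild type replicate 1, 2 or 3 (adjusted p = 0.0690, 0.178 and 0.212), without knockout replicate 2 or 3 (0.134 and 0.101) and in limma without the intensity trend (0.0916), while the difference stayed between -0.87 and -0.76.

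Among the genes ranked, each at its brightest tested probe set and without clone names or unnamed probe sets, some of which differed more, the largest differences lay in Y-linked genes. Eif2s3y, which encodes a translation initiation factor subunit, read 4.92 ± 0.40 in wild type and 11.30 ± 0.23 in knockout cells, an 83.4-fold higher signal. Uba1y and Uty were 28.4-fold and 26.2-fold higher, and for all 3 genes every knockout array lay above every wild type array. Among the other ranked genes, the ubiquitin-like modifier Ubd was 6.51-fold higher, the adaptor subunit gene Ap1s3 4.28-fold, the ribosomal protein paralog Rpl39l 3.20-fold, and Hemk1 and Zfp946 2.78-fold and 2.59-fold. The small GTPase gene Rab25 and the epithelial transcription factor gene Ovol2 were 2.86-fold and 2.72-fold higher. These rises passed limma's threshold at adjusted p from 1.40e-05 for Eif2s3y to 0.0341 for Ubd. The wild type means of Eif2s3y, Uba1y, Uty and Ubd (4.92, 4.14, 3.91 and 4.31) lay below the filter value of 5.27. The sizes of their folds therefore depend on dim signals.

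The deepest fall among the ranked genes was in Ccnb1ip1, a ubiquitin ligase gene known from meiotic crossing over, which went from 11.11 ± 0.24 to 7.66 ± 0.29, a signal 10.9-fold lower. Mpi, the mannose phosphate isomerase gene, was 7.93-fold lower, Trim34a 6.78-fold, the maternally expressed noncoding RNA Rian 6.41-fold and the proteoglycan gene Srgn 5.92-fold. Zfp42 (Rex1), a marker of naive pluripotent cells, went from 13.27 ± 0.13 to 11.28 ± 0.11, 3.98-fold lower. Galc, Tceanc2, Zeb1 and Rpl3l were between 3.77-fold and 3.39-fold lower, where Zeb1 encodes a repressor of epithelial genes. Adjusted p in limma ran from 8.37e-05 for Zfp42 to 0.0446 for Rpl3l, and Rpl3l missed the threshold (0.0526) when the genes of chromosomes 8 and Y were left out, an alternative chosen after the data were seen. Of these 20 genes, Eif2s3y, Uba1y, Uty, Ccnb1ip1, Mpi, Srgn, Zfp42 and Zeb1 kept their call with each array left out in turn. The other 12 genes kept their direction but lost the call without at least 2 of the arrays, with adjusted p there from 0.0525 (Ap1s3) to 0.268 (Rpl3l without wild type replicate 3). Galc, Tceanc2 and Rpl3l lost it without 5 of the 6. Trim34a and Rpl3l read 4.38 and 4.97 in knockout cells, below the filter value of 5.27, so their folds depend on dim signals. Probe sets too dim to be tested differed by 0.28 for Trim34a and by -0.05 and -0.24 for Galc, while those of Rian, Tceanc2 and Zeb1 were lower. Other tested probe sets missed the threshold, at -1.90 and -1.42 for Rian (limma adjusted p = 0.116 and 0.191) and -0.66 for Zeb1 (0.490).

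**Figure D2:**
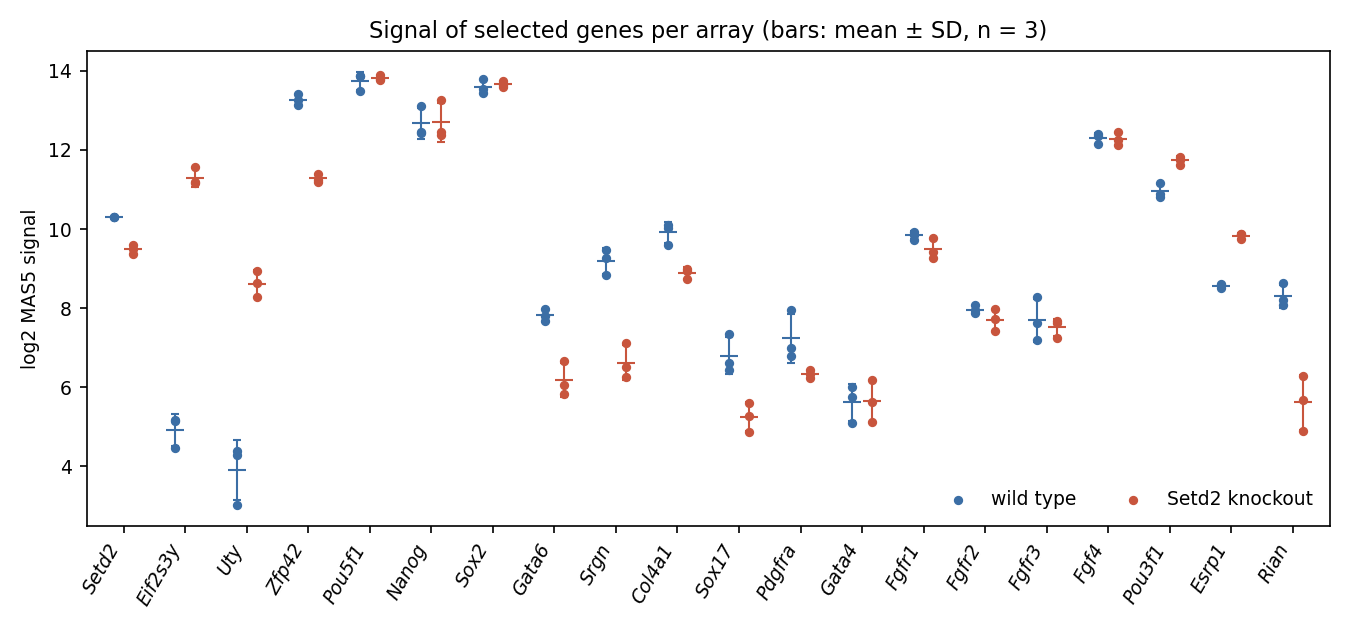
Log2 MAS5 signal of selected genes on each array (points), with mean ± SD of the 3 arrays per genotype (bars), wild type in blue and Setd2 knockout in red. Eif2s3y and Uty lie far higher in knockout cells, Zfp42, Gata6, Srgn and Rian lie lower, and Pou5f1, Nanog, Sox2 and Fgf4 overlap between the genotypes.

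In all, 74 probe sets were higher and 101 were lower in knockout cells (limma, 27022 tested), and 110 of these differed at least 2-fold, 49 higher and 61 lower. The genotypes also differed in Y-linked genes and, as described below, along chromosome 8. No gene or list difference given here can therefore be told apart from a difference between the cell lines. An unadjusted p under 0.05 was reached by 3153 probe sets. At 4904 probe sets, 18.1% of those tested, the 3 knockout values all lay on one side of the 3 wild type values, against 10% by chance if the 6 arrays were exchangeable, which the split by array number leaves doubtful. With the replicate number as a block the counts were 944 higher and 1185 lower, 364 of them at least 2-fold. All 175 probe sets called without the block were among these 2129 and kept their direction. Leaving out both arrays numbered 1, chosen after the data were seen, gave 914 higher and 1111 lower. Leaving out single arrays moved the total from 175 to 99, 46 and 33 without wild type replicate 1, 2 and 3, and to 437, 43 and 36 without knockout replicate 1, 2 and 3. Without the genes of chromosomes 8 and Y, 63 probe sets were higher and 64 lower (850 and 699 with the block).

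The primitive endoderm genes, to which the design refers, were lower as a list in knockout cells. Of 24 tested members, 3 fell and 0 rose: Srgn at -2.57 ± 0.26 (SE) on the log2 scale, Gata6 at -1.63 ± 0.26 and Col4a1 at -1.02 ± 0.17. Gata6 encodes a transcription factor that directs primitive endoderm fate, and Col4a1 a collagen of basement membranes. Adjusted over the list alone, 13 members fell. The list median was -0.54 (camera adjusted p = 6.67e-07, and 0.157 with an estimated correlation). Fry gave the list as lower too (adjusted p = 0.0248, and 0.0352 with the replicate block). With the replicate block 11 members fell and 1 rose. Every knockout array had a lower mean over the list than every wild type array. Col4a1 lies on chromosome 8, as do 3 of the 24 members in all, and without the genes of chromosomes 8 and Y the median was -0.49 (adjusted p = 5.94e-07).

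Single primitive endoderm factors differed from one another. Gata6 (1425464_at) read 7.82 ± 0.16 in wild type and 6.19 ± 0.44 in knockout cells. Its signal was 3.10-fold lower (limma adjusted p = 0.0372, and 0.00134 with the replicate block). Without the block its call was lost without wild type replicate 1, 2 or 3 (0.0776, 0.213 and 0.227) and without knockout replicate 3 (0.133). It was also lost without the filter on dim probe sets (0.0611) and without the intensity trend (0.0916). The call of Col4a1 (0.0457, and 0.000357 with the replicate block) was lost without replicate 2 or 3 of either genotype in the fit without a block. Adjusted p in limma there ran from 0.156 to 0.281, the highest without wild type replicate 3. The call was also lost under quantile normalization (0.0580), under centring on array medians (0.0645) and without the trend (0.118). Sox17 (1429177_x_at) differed by -1.55 (95% interval -2.32 to -0.78; adjusted p = 0.105 in limma; 0.0221 with the replicate block), while its other tested probe set differed by -0.11. Pdgfra, a receptor gene of the same lineage, differed by -0.91 (-1.63 to -0.19), short of the threshold also with the replicate block (adjusted p = 0.0601), and its other tested probe set by 0.64. Gata4 differed by 0.03 with an interval of -0.87 to 0.93. Its means of 5.62 in wild type and 5.65 in knockout cells lay near the filter value of 5.27. With so dim a signal and 3 arrays per genotype, a fall of this factor could be missed. No rise was detected, and the interval leaves room for one of up to 0.93. Sox17 was as dim in knockout cells, at 5.25.

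The core pluripotency factors showed no difference past the threshold. Pou5f1 differed by 0.08 (95% interval -0.17 to 0.32), Nanog by 0.02 (-0.57 to 0.62) and Sox2 by 0.07 (-0.16 to 0.30), each with a mean log2 signal above 12 in both genotypes and limma adjusted p of 0.857, 0.986 and 0.859. The SE of the Nanog difference was 0.26 in this fit and 0.065 with the replicate block, where its limma adjusted p was 0.869. Among 27 tested genes of naive pluripotency 1 fell, Zfp42, and 0 rose, with 2 lower when adjusted over the list alone. With the block 4 fell and 1 rose. The list median was -0.06 (camera adjusted p = 0.314; 0.144 with the block), and fry gave the list as lower with the block (adjusted p = 0.000539) but not without it (0.216). Zfp42 lies on chromosome 8.

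Genes of the Fgf receptor pathway, which drives cells of the inner cell mass towards primitive endoderm, were followed singly and as a list. Fgf4 differed by -0.02 (95% interval -0.27 to 0.23), Fgfr1 by -0.35 (-0.71 to 0.01), Fgfr2 by -0.26 (-0.70 to 0.18) and Fgfr3 by -0.18 (-0.83 to 0.46), with limma adjusted p from 0.443 to 0.974. Fgfr1 lies on chromosome 8. Of 33 tested genes of Fgf and Mapk signalling 1 fell, Phlda1, by 0.94 ± 0.15 (SE) on the log2 scale. Its limma adjusted p was 0.0358, and 0.000192 with the replicate block. Without the block the call was lost without each array but knockout replicate 1 (adjusted p from 0.0778 to 0.227). Adjusted over the list alone 1 rose and 2 fell, with the replicate block 4 rose and 2 fell, and the list median was -0.12 (camera adjusted p = 0.365).

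Genes of the primed epiblast were higher as a list, with a median of 0.39 over 20 tested members (camera adjusted p = 0.0101, and 0.471 with an estimated correlation). In fry the list missed the threshold (adjusted p = 0.102) and passed only with the replicate block (adjusted p = 0.0352). Pou3f1 (Oct6), a transcription factor gene of the epiblast, rose by 0.78 ± 0.12 (SE), 1.71-fold, and was the 1 member past limma's threshold, with 5 higher when adjusted over the list alone. With the replicate block 10 members rose and 1 fell. The list's call was lost without wild type replicate 1 (adjusted p = 0.0851) and without knockout replicate 2 (0.0562). The call of Pou3f1 was lost without wild type replicate 2 or 3 (0.199 and 0.227), without knockout replicate 2 or 3 (0.178 and 0.110) and without the intensity trend (0.139). With all arrays and the replicate block its limma adjusted p was 0.000470.

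The genes of mismatch repair and homologous recombination were lower as a list by a small amount, with a median of -0.20 over 23 tested members (camera adjusted p = 0.00879, and 0.333 with an estimated correlation). In fry the list missed the threshold (adjusted p = 0.0507, and 0.0610 with the replicate block). None of them passed limma's threshold, with the count also at 0 over the list alone, and 1 rose and 2 fell with the replicate block. The brightest members, Msh6, a mismatch recognition protein that binds H3K36me3, and Chek1, a checkpoint kinase, differed by -0.19 (95% interval -0.34 to -0.04) and -0.21 (-0.43 to 0.02). Other tested probe sets of Chek1 differed by -0.25, -0.37 and -1.12 (limma adjusted p = 0.448, 0.475 and 0.197). The last of these passed with the replicate block (limma adjusted p = 0.0300).

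The other 31 lists gave camera adjusted p from 0.0753 to 0.990. Among 34 imprinted genes, Rian fell by 2.68 and Zdbf2 by 0.97 on the log2 scale and Impact (1415911_at) rose by 0.80, with 3 higher and 5 lower when adjusted over the list alone, 3 higher and 7 lower with the replicate block, and a list median of -0.05 (adjusted p = 0.577). Of 24 readers and partners of H3K36me3 1 fell, the histone deacetylase gene Hdac1, by 0.70 ± 0.10 (SE), with a list median of -0.03. With the block 2 readers rose and 3 fell. Of 17 enzymes that set or remove H3K36 methylation 1 fell, Setd2 itself, with 1 lower and 1 higher over the list alone and with the block. Of 28 splicing factors 1 rose, the epithelial splicing regulator Esrp1, from 8.57 ± 0.04 to 9.82 ± 0.07, a 2.39-fold higher signal (limma adjusted p = 0.00602). Of 23 targets of p53 1 rose, Ccng1, by 0.45 ± 0.07 (SE), and the list median was 0.17 (adjusted p = 0.0753). With the block 4 p53 targets rose and 1 fell. The p53 list passed without wild type replicate 2 (0.0486) and without knockout replicate 2 or 3 (0.0385 and 0.0303). The calls of Zdbf2, Impact, Hdac1 and Ccng1 were lost without each array but knockout replicate 1 (0.0575 to 0.254), and that of Esrp1 without replicate 3 of either genotype (0.0573 and 0.0546). A second Impact probe set (1446750_at) fell by 2.44, and Riok3 likewise had probe sets past the threshold in both directions, at 0.97 and -2.39.

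Genes near Setd2 on chromosome 9 gave 0 of 22 tested members past limma's threshold, also over the list alone, and 3 fell with the replicate block. The brightest members, Tdgf1, a Nodal coreceptor gene, and Smarcc1, a chromatin remodelling subunit gene, differed by -0.11 and -0.09. The list median was -0.14 (camera adjusted p = 0.102; adjusted p = 0.471 with an estimated correlation). The list passed without knockout replicate 3 (0.0465) and when the genes of chromosomes 8 and Y were left out (0.0373), an alternative chosen after the data were seen.

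Markers of feeder fibroblasts did not part the genotypes. Of 27 tested markers 0 passed limma's threshold in either direction, and 0 did so over the list alone. With the replicate block 2 rose and 1 fell. The list median was -0.07 and the mean -0.02, while camera gave the direction as up (adjusted p = 0.967), and the list passed as higher without knockout replicate 1 (0.0413). The brightest marker, Fn1, differed by 0.43 (95% interval 0.20 to 0.67; adjusted p = 0.128; 0.00327 with the replicate block), and Acta2 by -0.23 (-1.61 to 1.14). By array number the same markers did differ: their mean level was 7.80 and 7.57 on the arrays numbered 1 and between 8.34 and 8.76 on the other 4.

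**Figure D3:**
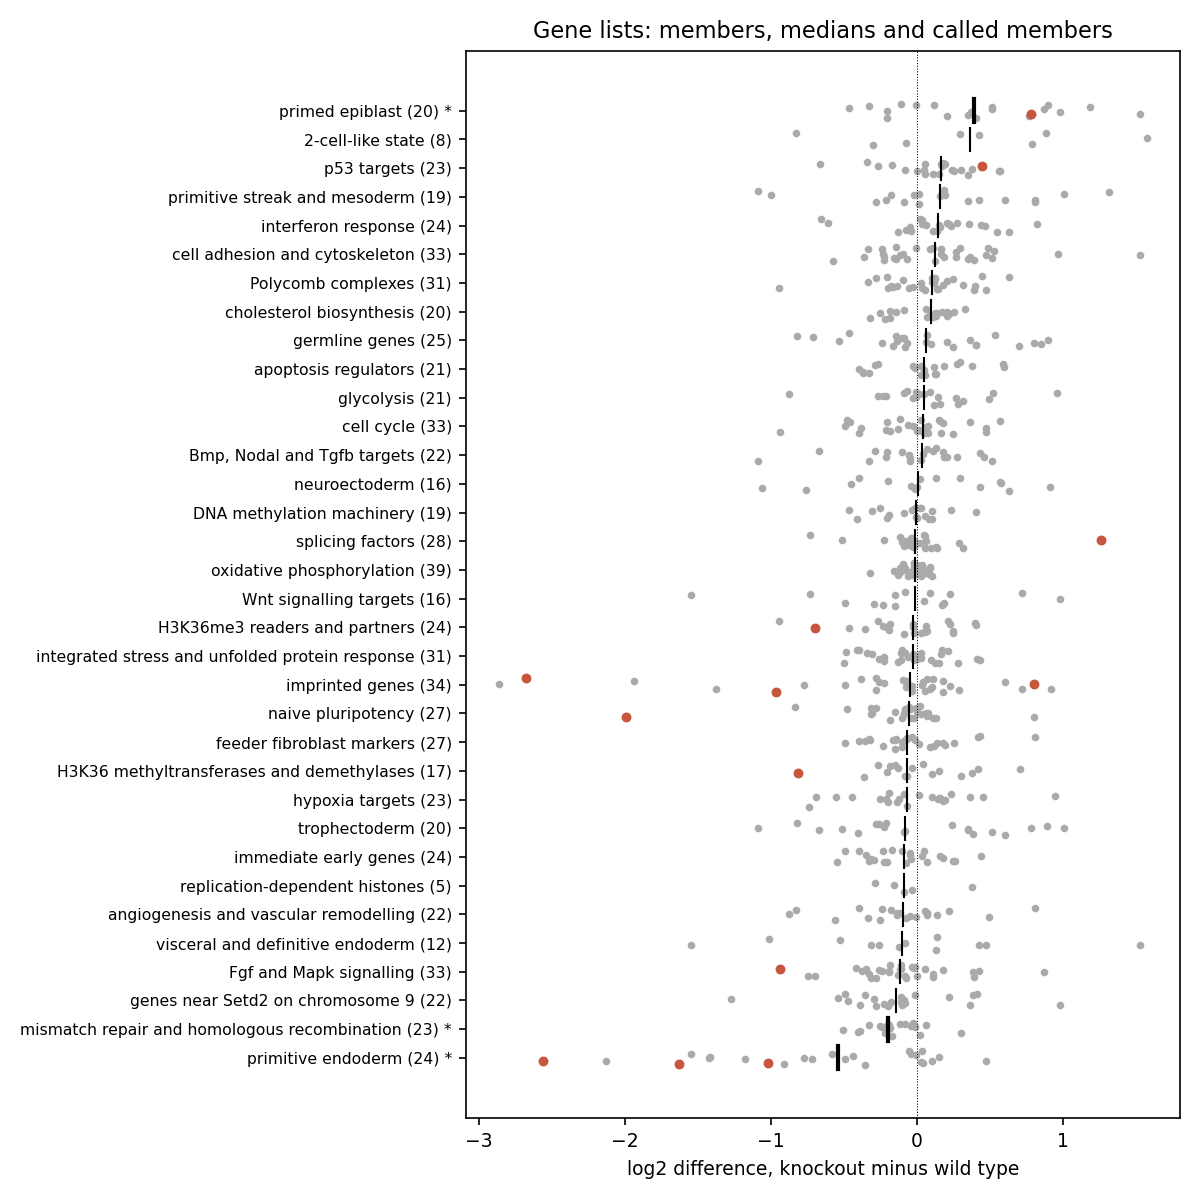
Log2 difference, knockout minus wild type, of each tested member (points) of 34 gene lists, with the list median (bar) and the number of members in brackets; red points passed the threshold in limma, and heavy bars and asterisks mark the 3 lists past camera's threshold. The primitive endoderm list has the lowest median, at -0.54, and the primed epiblast list the highest, at 0.39.

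Chromosome 8 stood apart from the other chromosomes. Its 709 tested genes had a median difference of -0.34, with 86.3% below 0 against 48.0% of the genes of the other autosomes and X. The 95% bootstrap interval of this median was -0.36 to -0.32, drawn over genes, which are not independent replicates. The medians of the other chromosomes ranged from -0.03 to 0.04, with X at 0.04. Chromosome 8 was the 1 chromosome of 20 past camera's threshold (adjusted p = 1.27e-31; adjusted p = 0.00930 with an estimated correlation; 0.319 with an estimated correlation and the replicate block). Between single wild type and knockout arrays the median ranged from -0.38 to -0.27 over the 9 pairs. It was -0.32 within number 1 and -0.37 within numbers 2 and 3.

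Genes of chromosome 8 made up a large part of those that fell. Of 62 genes that fell, 26 lay on chromosome 8 (41.9%), against 5.49% of the genes tested (Fisher's exact test, two-sided, p = 3.47e-17, over genes, which are not independent replicates), and 0 of 33 genes that rose lay there. With the replicate block 270 of 742 genes that fell lay on chromosome 8, and 0 of 533 that rose. Zfp42 and Col4a1 were among them.

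**Figure D4:**
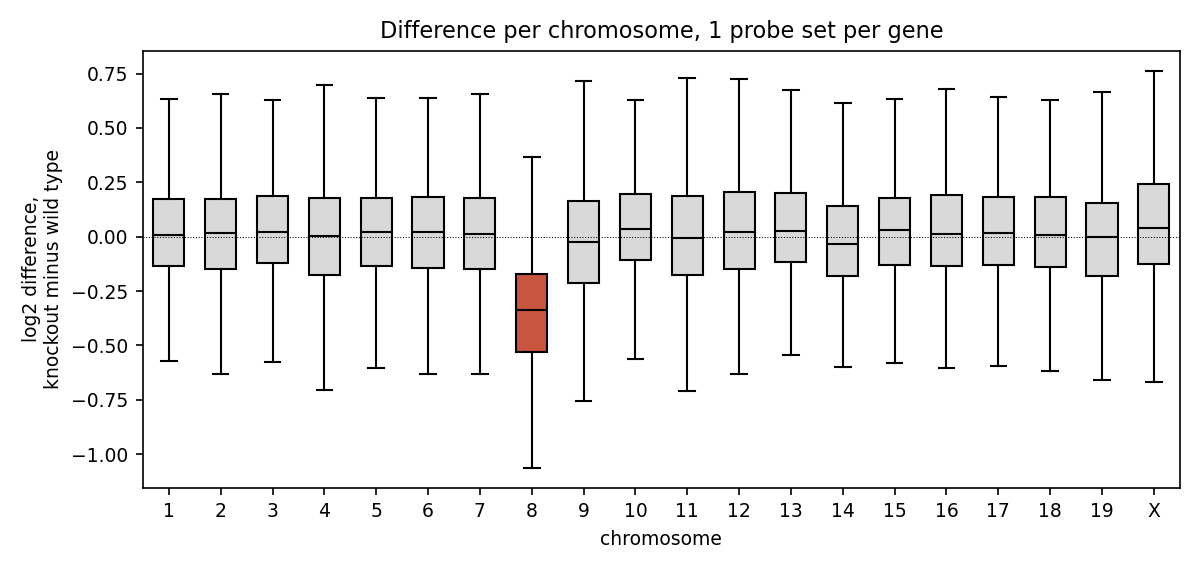
Log2 difference, knockout minus wild type, of the tested genes of each autosome and the X chromosome, with the median (line), the quartiles (box) and whiskers to the last gene within 1.5 box lengths. Chromosome 8, in red, has a median of -0.34, and the other medians lie between -0.03 and 0.04.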

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

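Of the alternatives, the block for number 1 against numbers 2 and 3, leaving out both arrays numbered 1, leaving out the genes of chromosomes 8 and Y, and the pseudocount at the 25th percentile were chosen after seeing the data, as was the choice of which uncalled lists to follow, and with it of Fn1 and Acta2. The counts moved with how the spread between arrays was modelled, and the cause was not tested beyond the split by number. Higher, lower and at least 2-fold probe sets numbered 30, 27 and 56 without the intensity trend and 580, 774 and 364 with array weights. With number 1 against 2 and 3 as a block they were 986, 1256 and 366, and without both arrays numbered 1 914, 1111 and 416. Without the genes of chromosomes 8 and Y 64 were lower, fewer by construction, and the genes near Setd2 passed as a 4th list, and with the replicate block added there 850, 699 and 317 passed, with 5 lists. Single arrays left out gave 17 to 160 higher, 14 to 277 lower and 32 to 210 at least 2-fold, 2 to 5 lists and 1 to 2 chromosomes. The Setd2 difference ranged from -0.87 to -0.76 there and kept its size of -0.82 without the trend, where its adjusted p was 0.0916. Without the trend 15 other genes followed lost their calls: Ubd, Rpl39l, Rab25, Zfp946, Trim34a, Rian, Tceanc2, Gata6, Pou3f1, Col4a1, Phlda1, Hdac1, Zdbf2, Impact and Ccng1 (adjusted p from 0.0526 for Zfp946 to 0.252 for Ccng1). Centring on array medians ended those of Rpl3l, Col4a1, Zdbf2, Impact and Ccng1 (0.0545 to 0.0890). With no filter and with a pseudocount at the median the Y chromosome passed beside chromosome 8, which made 2. With an estimated correlation 0 lists passed in limma's camera, against 3 at the preset value; at an unadjusted p under 0.05 the same 3 lists passed there. A 4th list passed with the mean of a gene's probe sets (p53 targets, adjusted p = 0.0372), without both arrays numbered 1 (glycolysis) and without the filter (Y-linked genes and Xist). The medians of the primitive endoderm list (-0.66 to -0.54) and chromosome 8 (-0.36 to -0.33) kept direction and call without any single array.

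With the replicate block 944 probe sets were higher, 1185 lower and 364 at least 2-fold, and among the genes followed under every alternative the calls of Sox17 and Fn1 were gained and none was lost. No call of a list or chromosome changed with the block at the preset correlation.

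Signs turned for values near 0. Pou5f1 was at -0.0506 to 0.143 without single arrays, lowest without wild type replicate 1, and -0.0253 without both arrays numbered 1. Nanog was at -0.0201 with array weights, -0.0352 without both arrays numbered 1, and -0.26 to 0.25 without single arrays. Sox2 reached -0.0119 to 0.17 without single arrays. Gata4 was at -0.0332 under quantile normalization, -0.0608 with array weights and -0.25 to 0.29 without single arrays. Fgfr3 was at 0.0337 with array weights, 0.0517 without both arrays numbered 1 and -0.44 to 0.10 without single arrays, Fgf4 at -0.10 to 0.0541 and Acta2 at -0.72 to 0.46. The feeder marker median was 0.00637 with array weights, 0.0870 without both arrays numbered 1 and -0.34 to 0.40 without single arrays. The imprinted gene median was 0.000190 without _x_at and _s_at probe sets. Leaving out 1 array numbered 1 leaves the split by number unbalanced between the genotypes. In numbers 2 and 3 minus number 1, Nanog was at -0.76 and the feeder marker median at 1.10. Without knockout replicate 1 their genotype differences were -0.26 and 0.40, and without wild type replicate 1 0.25 and -0.34, the directions this imbalance gives. No cause was tested for the other values. Without the filter on dim probe sets Ubd, Rpl3l, Gata6 and Ccng1 lost their calls, for which no cause was tested either.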

Other observations

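The tests of feeder RNA, of single regulated genes and of the number split were chosen only after the result was seen, as were the comparison by array number and the leaving out of chromosome 8 from the tests of X-linked and long genes; the tests of gene length, of other splits of the arrays, of X dose and of 4 stretches of chromosome 8 were set before their own values were computed, those of X dose and of the stretches after the pattern they address had been seen.

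The arrays numbered 2 and 3 differed from those numbered 1 in many genes in both genotypes: 5768 probe sets passed the threshold, 2711 higher and 3057 lower in numbers 2 and 3 (limma, genotype in the model). Fibroblast genes were higher there, with 16 of 27 feeder markers higher and 2 lower; S100a4 was higher by 2.17 ± 0.27 (SE), Col3a1 by 2.05 ± 0.23 and Acta2, the smooth muscle actin, by 1.77 ± 0.15. Genes of cholesterol biosynthesis went the other way, with 10 of 20 lower and 0 higher, among them Dhcr7 (-0.87), Msmo1 (-0.84) and Hmgcs1 (-0.55), and a list median of -0.37. Of 24 immediate early genes 12 were lower, with Gadd45b at -1.37 and Fos at -2.30, and 3 higher. Of 28 splicing factors 10 were higher, led by Mbnl1 at 0.93, and 1 lower. In camera these 4 lists passed at adjusted p from 1.68e-06 to 0.0155, and none did with an estimated correlation (adjusted p = 0.615 for each). Among naive pluripotency genes Nanog (-0.76), Tcl1 (-1.22) and Tfcp2l1 (-1.20) were lower in numbers 2 and 3, while Gdf3 (1.38) and Lin28a (0.70) were higher. Meiotic and germline genes were lower in part: Stra8 by -1.15, Sycp3 by -1.01 and Dazl by -0.88 on the log2 scale, with 8 of 25 lower and 1 higher (camera adjusted p = 0.0863). The genes in this paragraph were chosen after their values were seen.

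Between the genotypes, some further genes outside the naming rule were singled out after their values were seen. Beside Rian, the other maternally expressed RNAs of its cluster, Meg3 and Mirg, differed by -1.94 and -2.86 (limma adjusted p = 0.127 and 0.210; 0.00884 and 0.0282 with the replicate block), while Dlk1, expressed from the paternal copy, differed by -0.04. AI662270 was higher by 5.45 and 5.46 at its 2 probe sets, from 6.24 ± 0.26 to 11.68 ± 0.27 at the first. Pclaf, a PCNA-binding factor gene, fell by 4.28 at its dimmer probe set and differed by 0.06 (95% interval -0.20 to 0.32) at its brighter one. Why probe sets of Pclaf, Impact or Riok3 part was not tested.

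The Y-linked genes Eif2s3y, Uty and Uba1y read high on all 3 knockout arrays and low on all 3 wild type arrays. The probe sets of Kdm5d, Zfy2, Sry and Usp9y were too dim to be tested. Usp9y read 3.88 in wild type and 6.29 in knockout cells, with no overlap between the genotypes. The others were mixed, at 0.79, -1.21 and -0.76 for Kdm5d, -0.66 and 1.12 for Sry and 0.21 for Zfy2. The tested probe set of Orly differed by 0.31 (limma adjusted p = 0.768). A dose of 2 active X chromosomes in the wild type cells would put X-linked genes lower in knockout cells by a clear margin. Yet the X median minus the autosome median was 0.03 (0.0282 over 419 X-linked genes, chromosome 8 left out). The 95% bootstrap interval was 0.00307 to 0.0650, drawn over genes, which are not independent replicates. Male feeder cells left only in the knockout cultures would have raised fibroblast markers along with Y-linked genes, but the 27 markers had a median difference of -0.0685 and ranged from -0.49 to 0.81, against at least 3.30 for the Y-linked probe sets called. This holds if both cultures used like feeders. What stays open, as an untested hypothesis, is a difference between the lines themselves, such as female cells with a single X or loss of the Y chromosome in the wild type line, and it cannot be separated here from the Setd2 genotype.

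Chromosome 8 genes were lower as a set in knockout cells, and this pattern was seen before any explanation was written. A few strongly regulated genes cannot account for it, since 86.3% of its 709 tested genes lay below 0. A number split shared by both genotypes cancels from the difference by design, since each genotype has 1 array of each number. The medians within number 1 and within numbers 2 and 3, at -0.32 and -0.37, show only that the difference was present in both. A difference in dose along the whole chromosome may be the source, as a hypothesis: 4 stretches of the chromosome with like numbers of genes had medians of -0.32, -0.31, -0.37 and -0.34, the highest being -0.31. The brighter genes had a median of -0.35, short of the -0.58 that 2 copies against 3 would give in every cell with no loss in the array's scale, so the size of any dose difference stays open. Genotype and line are the same split of these arrays, so an effect of Setd2 loss on this chromosome was not tested. Zfp42 and Col4a1 differed by -1.99 and -1.02, beyond the chromosome median of -0.34. How much of their falls belongs to the shift of the chromosome was not tested.

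The difference between number 1 and numbers 2 and 3 had no counterpart in the labels, and no explanation other than feeder RNA was tested. More feeder RNA in numbers 2 and 3 may account for the fibroblast genes: their median was 1.10 higher there, but with an estimated correlation this list gave p = 0.176, so it cannot be told apart from other shared variation. Of the 27 markers, 4 stood on another list, 5 (Fn1, Acta2, Tagln, Sparc and Mmp2) lay above the median gene even on the arrays numbered 1, and among the brightest Fn1 differed by -0.19, Sparc by -0.35 and Acta2 by 1.77. The gelatin step of the protocol would remove most feeders. Feeder RNA as the whole of the difference is argued against by 4 naive pluripotency genes (Gdf3, Lin28a, Utf1 and Sall4) that were higher by at least 0.3 log2 in numbers 2 and 3 past the threshold, since such RNA would dilute stem cell genes, although 11 of the 27 naive genes were lower there and 5 higher, with a median of -0.18, the direction dilution would give.

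A further hypothesis was that long genes, over which H3K36me3 extends furthest, would be lower without Setd2. The longest 25% of genes (3038 genes, chromosomes 8 and Y left out) had a median 0.02 above that of the other genes (0.0204; camera with an estimated correlation, p = 0.707), the opposite direction.

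Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. For probe sets higher, lower and at least 2-fold, 1 of the 10, the real split, reached its count (74, 101 and 110 against 0 in each other split). For gene lists 7 of the 10 gave at least the 3 lists of the real split, with 7 the most in another split, and for chromosomes all 10 gave at least 1. Every other split puts arrays of both genotypes on each side. Part of the genotype difference then adds to the spread, and part can stay between the sides. The counts of those splits therefore do not measure what chance alone gives. With the replicate block the real split gave 2129 probe sets and the 3 other splits that part all 3 pairs gave 0; those splits mix the genotypes on each side.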
